A study of Homo sapiens with 21 samples.

How the data were processed

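RNA was measured by bulk sequencing in 21 libraries of AsPC-1 cells kept in suspension culture, in 7 groups of 3 libraries. Per the labels, cells in wells of 6-well plates received DMSO vehicle or 25 nM LGK974 for 4 h, 24 h or 72 h, or 1 µM LGK974 for 24 h, and were treated again every 24 h. Total RNA was extracted with a Zymo Quick-RNA kit and made into standard Illumina libraries. The labels do not state the strand or a poly(A) selection, so transcripts that overlap on opposite strands cannot be told apart here.

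The authors deposited RSEM expected counts per gene symbol for all libraries in a single file, not normalized. The submitters' processing notes name Bowtie2 2.2.9, RSEM 1.2.25, HTSeq 0.5.3p9, edgeR without a version and DESeq2 2.6.10, with the genome hg19. They give no order or role for the tools, no annotation, no filter and no rule for reads with several matches. The authors also deposited 4 tables of log2 fold changes, per the file headers. The p-value in these deposited tables is adjusted by the Benjamini-Hochberg method, per the file headers, and which tool made the tables is not stated. Their fold changes are narrower than those computed here from the counts. The deposited fold changes were set beside those from the counts and enter no test. Gene symbols were used as they stand in the files, and no coordinates were used, since the files rest on hg19 and the reference at hand is GRCh38.

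The count file holds 25343 gene entries. Of these, 28 have symbols that a spreadsheet turned into dates and were left out, with 0.18% to 0.19% of the counts of each library, and 25315 were used. Totals were 9019030 to 14620500 per library. The 10 most abundant genes held 5.39% to 6.56% of each library. Between libraries of a group, the chi-square per degree of freedom was 1.89 to 4.91, so spread exceeds counting noise. Genes with near-identical copies, read-through loci and pseudogenes share reads, and are named only with that limit.

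Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, statmod 1.5.0). Genes were kept by filterByExpr by group with a minimum count of 10 and a minimum total of 15, which left 13602. Levels are given in CPM, on scaled library sizes. Libraries were scaled by the trimmed mean of M values. All 7 groups shared 1 quasi-likelihood fit with group means and no other covariate, with 14 residual and 10.7 prior degrees of freedom. Genes with an adjusted p (Benjamini-Hochberg over all genes tested) under 0.05 were called. The 9 comparisons were treatment against vehicle at each time, 1 µM against vehicle, 1 µM against 25 nM, the differences of the 25 nM effect between 24 h and 4 h and between 72 h and 24 h, and vehicle between successive times.

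Before the data were examined, 34 gene lists were fixed. Lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, with adjusted p over the lists of a comparison, and again with an estimated correlation. The 4 lists with fewer tested members, markers of other cell types and of RNA quality, were left out of camera. Members were counted by adjusted p over all genes and adjusted over the list alone.

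Genes are named by a rule fixed with the lists. Per comparison, it takes the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 1 and no overlap between the groups' CPM values, and the 4 members of each list with the smallest p. For the differences between times it takes the 4 largest in each direction without the criterion on overlap. It adds AXIN2, NKD1, RNF43, ZNRF3, LGR5, NOTUM, MYC, CCND1 and PORCN in every comparison, and for the dose comparison the genes of each dose against vehicle. Genes named outside the rule are marked as picked after their values were seen. Some genes that the rule names are not reported here.

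The test was tested on simulated data with 225 genes changed: 200 single genes, 50 at each fold of 1.25, 1.5, 2 and 3, and an added list of 25 genes lowered 1.25-fold. For the 24 h groups edgeR called 163 genes, 6 of them false (3.68%), and recovered 56%, 70%, 84% and 90% of the 50 single genes at each of these folds, the added list not counted. For the 4 h groups it called 161, with 3 false (1.86%) and 50%, 62%, 82% and 90% recovered. For the doses it called 147, with 6 false (4.08%) and 40%, 64%, 76% and 78% recovered. Camera at the preset correlation passed the added list in all 3 simulations. It also passed 1 other list for 4 h, 2 for 24 h and 4 for the doses, none of which had been changed as a set, though single changed genes may be among their members.

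Alternatives were relative log expression scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in every library of a group, a fit of only the groups compared, the replicate number as a block, each library left out in turn, a change of at least 2-fold, and an adjusted p under 0.01. For the lists, fry was run besides. The effect of leaving out both libraries with the lowest values on the fourth component, and camera on the differences between times, were added after the data were seen. Overlap of calls between doses was set beside 20 simulations of unchanged groups against the shared vehicle libraries. The count of called genes was compared with that of other groupings of the same libraries, all 10 for a comparison of 2 groups and 100 for a difference between times.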

Results

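AsPC-1 cells, an established pancreatic ductal adenocarcinoma line kept in suspension on ultra-low-attachment plates, were treated with LGK974, an inhibitor of the acyltransferase PORCN, which Wnt ligands need for secretion. Bulk RNA sequencing covered 21 libraries in 7 groups with 3 libraries each. DMSO vehicle and 25 nM LGK974 were sampled at 4 h, 24 h and 72 h, and 1 µM LGK974 was sampled at 24 h only. Each library held 9019030 to 14620500 expected counts, and 13602 genes passed the filter on low counts. The labels describe the libraries of a group as wells of 6-well plates and name no separate cultures, so every p-value here measures the spread between these wells, which may be technical. The biological coefficient of variation between the wells of a group was 5.46%. Changes are log2 fold changes ± standard error from edgeR with n = 3 libraries per group, and a gene is said to rise or fall only where its adjusted p is under 0.05.

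The first principal component held 49.4% of the variance and ordered the groups by time and treatment. Its mean ± SD over 3 libraries was -53.1 ± 1.69 in vehicle and -48.7 ± 1.01 with 25 nM at 4 h. At 24 h it was -3.67 ± 1.64 in vehicle, 9.70 ± 1.72 with 25 nM and 6.74 ± 2.05 with 1 µM. At 72 h it was highest, and higher with 25 nM than in vehicle. The second component held 9.73% and the third 7.93%. On the fourth, with 3.11%, replicate 2 of 25 nM at 4 h had the lowest value (-21.5), and the vehicle libraries at 72 h were spread from -17.7 (replicate 3) to 20.5 (replicate 2).

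**Figure D1:**
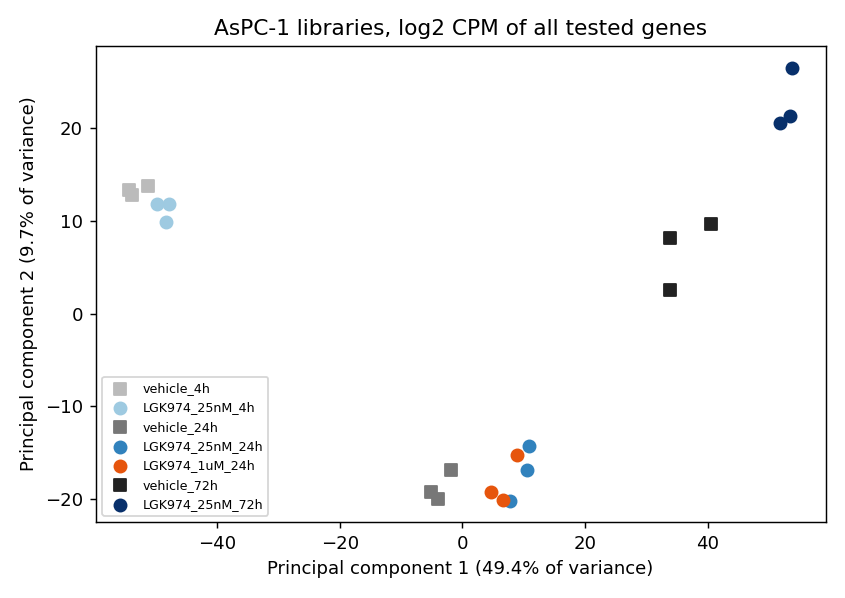
First against second principal component of log2 CPM, one point per library and 3 per group. The first axis (49.4% of the variance) separates the times, and within each time the treated libraries sit to the right of their vehicle libraries.

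The comparison at 4 h asks which genes respond early to the block of Wnt secretion. AXIN2, a direct target of beta-catenin that feeds back on the pathway, stood closest to a call and was lower in all treated wells than in all vehicle wells. RNF43, a ubiquitin ligase that removes Frizzled receptors from the cell surface, had a lower estimate too. So did MYC, a transcription factor of cell growth, and BMP4, a secreted ligand and Wnt target. MUC5B, a gel-forming mucin, had a higher estimate.

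AXIN2 measured 4.75 to 6.35 CPM in the 3 vehicle libraries and 1.80 to 2.53 with 25 nM, a log2 fold change of -1.41 ± 0.24 (edgeR adjusted p = 0.0553). RNF43 changed by -0.75 ± 0.17 (edgeR adjusted p = 0.332), BMP4 by -0.40 ± 0.08 (edgeR adjusted p = 0.150) and MYC by -0.27 ± 0.06 (edgeR adjusted p = 0.179). MUC5B changed by 0.47 ± 0.11 and ZNRF3, the ligase related to RNF43, by 0.22 ± 0.17. PORCN itself changed by -0.09 ± 0.09. edgeR called 0 of 13602 genes, with 723 at an unadjusted p under 0.05 (5.32%). DESeq2 called 6, among them AXIN2 (-1.42, adjusted p = 0.0202), BMP4 (-0.40, adjusted p = 0.0202), MYC (-0.27, adjusted p = 0.0202) and ZNF703 (-0.27, adjusted p = 0.0288), a transcriptional repressor. DESeq2 gave its smallest adjusted p to the read-through locus RAB4B-EGLN2 (-22.2, adjusted p = 4.49e-09) and the pseudogene NUDT4P1 (25.7, adjusted p = 3.59e-06). Folds of that size cannot be read as effects. These loci, ZNF703 and RPL21P28, a ribosomal protein pseudogene that shares reads with its parent gene, lie outside the naming rule and were picked after their values were seen. limma-voom called 2, AXIN2 (-1.40, adjusted p = 0.0284) and RPL21P28. With no filter on low counts edgeR called 28 genes, with a stricter filter 1, and with only these groups in the fit 11. The 1 gene called with the stricter filter was AXIN2 (edgeR adjusted p = 0.0370). AXIN2, BMP4, MYC and MUC5B are among both the 28 and the 11, and RNF43 is among the 28. Read-through and pseudogene-type loci are among the 28 and the 11 too. Without vehicle 4 h replicate 1 edgeR called 1, RPL21P28 (2.14, edgeR adjusted p = 0.000468). The groups did not overlap for 1496 of 13602 genes, where chance gives 10%.

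None of the fixed gene lists held a called member at 4 h, and of 30 lists tested 5 passed at the preset correlation and 0 with an estimated one. Without vehicle 4 h replicate 1 or 2, or 25 nM 4 h replicate 1, the count at the preset correlation was 2, 1 and 2, and over all left-out libraries it was 1 to 7; with no filter on low counts it was 3. Of 24 MAPK and immediate early genes, 3 were lower when adjusted over the list alone. Camera placed this list lower (adjusted p = 0.000398 at the preset correlation, adjusted p = 0.411 with an estimated correlation). The members with the smallest p were MYC, IER3 (-0.21 ± 0.06), a survival gene, the ERK phosphatase DUSP6 (-0.13 ± 0.04) and PHLDA1 (-0.08 ± 0.03). Of 21 Wnt/beta-catenin target and feedback genes, 5 were lower adjusted over the list alone. Camera placed the Wnt list lower, while its median was -0.01 and its mean 0.03 (adjusted p = 0.0226, and adjusted p = 0.581 with an estimated correlation). That camera call was lost without vehicle 4 h replicate 1 (adjusted p = 0.0647), vehicle 4 h replicate 2 (0.0517) or 25 nM 4 h replicate 2 (0.223), and with no filter on low counts (0.0685). Mucins and goblet-type secretory genes leaned higher, with 1 of 18 higher adjusted over the list alone (camera adjusted p = 0.00483, and adjusted p = 0.581 with an estimated correlation). Without vehicle 4 h replicate 2 the mucin list had a camera adjusted p of 0.120, and without 25 nM 4 h replicate 1 it had 0.110.

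At 24 h the comparison of 25 nM with vehicle asks what follows once the block has lasted a day. Genes of Wnt feedback fell together: AXIN2, the receptor-clearing ligases RNF43 and ZNRF3, NKD1, which binds Dishevelled and dampens the signal, and the R-spondin receptors LGR5 and LGR6. MYC and BMP4 fell with them, as did CLDN2, a pore-forming claudin of leaky epithelia, GPX2, a glutathione peroxidase of the gut, and RAB15, a GTPase of endosome recycling. GUCA2A, the gut peptide guanylin, rose, as did PCK1 of gluconeogenesis, the stress keratin KRT16 and CABP1, a calcium-binding protein. BMF, which promotes cell death, and the cell cycle inhibitor CDKN1A rose as well.

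CLDN2 changed by -3.51 ± 0.27 (edgeR adjusted p = 1.43e-09) and AXIN2 by -3.16 ± 0.29 (edgeR adjusted p = 1.19e-08). RNF43 changed by -2.34 ± 0.19, GPX2 by -2.22 ± 0.24, BMP4 by -1.98 ± 0.08 and RAB15 by -1.88 ± 0.17. NKD1 changed by -1.73 ± 0.37, LGR6 by -1.36 ± 0.08, ZNRF3 by -1.13 ± 0.18 and MYC by -0.73 ± 0.06. LGR5 changed by -2.62 ± 0.57 at a low level, 0.853 to 2.04 CPM in vehicle and 0.0854 to 0.383 with 25 nM. CCND1, a cyclin and Wnt target, changed by -0.20 ± 0.04, and PORCN rose by 0.36 ± 0.10 (edgeR adjusted p = 0.00663). NOTUM, a secreted enzyme that inactivates Wnt ligands, changed by 0.05 ± 0.44 and was not called. GUCA2A rose by 1.75 ± 0.32 (edgeR adjusted p = 0.000172), PCK1 by 1.60 ± 0.31, CABP1 by 1.59 ± 0.36, KRT16 by 1.53 ± 0.10, BMF by 1.45 ± 0.15 and CDKN1A by 0.42 ± 0.07. edgeR called 3687 genes, 2076 higher and 1611 lower, of which 47 and 87 changed at least 2-fold. The groups did not overlap for 5567 genes (40.9%, against 10% by chance).

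LOC100093631, a locus of the GTF2I pseudogene type whose reads can belong to its relatives, rose by 2.43 ± 0.74. Its call was lost without vehicle 24 h replicate 2 (2.23, edgeR adjusted p = 0.0706), without vehicle 24 h replicate 3 (2.12, edgeR adjusted p = 0.0758) and under DESeq2 (adjusted p = 0.0814). CGB5, a chorionic gonadotropin gene with near-identical copies, rose by 1.55 ± 0.49. Its call was lost without vehicle 24 h replicate 1 (1.00, edgeR adjusted p = 0.0814), without 25 nM 24 h replicate 2 (1.49, edgeR adjusted p = 0.0503), without 25 nM 24 h replicate 3 (1.24, edgeR adjusted p = 0.119) and with only these groups in the fit (edgeR adjusted p = 0.0564).

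The growth program fell at 24 h. All 25 DNA replication and S phase genes fell, the same 25 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 8.04e-37, and adjusted p = 0.0155 with an estimated correlation). They include the origin licensing factor CDC6 (-0.86 ± 0.08), the helicase subunit MCM7 (-0.69 ± 0.06) and RRM2 (-0.69 ± 0.07), which makes deoxynucleotides. Of 30 MYC-linked ribosome biogenesis genes 26 fell, and 29 fell adjusted over the list alone (camera adjusted p = 2.00e-26, and adjusted p = 0.0227 with an estimated correlation). Among them, DKC1 of RNA pseudouridylation changed by -0.57 ± 0.06 and nucleolin, NCL, by -0.54 ± 0.05. Of 19 homologous recombination and Fanconi repair genes 17 fell, and 17 adjusted over the list alone (camera adjusted p = 2.37e-11, and adjusted p = 0.0220 with an estimated correlation). EXO1, a resection nuclease, changed by -0.96 ± 0.13, the helicase BLM by -0.92 ± 0.13 and BRCA1 by -0.64 ± 0.09. Of 25 mitosis genes 20 fell, and 21 adjusted over the list alone (camera adjusted p = 1.05e-12, and adjusted p = 0.0939 with an estimated correlation). The proliferation marker MKI67 changed by -0.49 ± 0.06 and cyclin A2, CCNA2, by -0.61 ± 0.08.

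Of 21 Wnt/beta-catenin target and feedback genes, 13 fell, 4 rose and 4 were not called. Adjusted over the list alone, 14 fell and 5 rose (camera adjusted p = 1.60e-10, and adjusted p = 0.0155 with an estimated correlation). Of 17 TGF-beta targets 7 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.00945, and adjusted p = 0.0477 with an estimated correlation). ID1, an inhibitor of differentiation factors, rose by 0.33 ± 0.04, while PMEPA1, which dampens SMAD signaling, changed by -0.21 ± 0.04. Some markers of gland and gut differentiation rose too, though their lists did not pass with an estimated correlation. Of 22 classical pancreatic cancer subtype genes 12 rose and 1 fell, and 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.78e-05, and adjusted p = 0.201 with an estimated correlation). The trefoil factor TFF2 rose by 0.65 ± 0.08 and the cadherin CDH17 by 0.44 ± 0.04, whereas lysozyme, LYZ, changed by -0.96 ± 0.13. Of 18 mucins and goblet-type secretory genes 8 rose, and 8 adjusted over the list alone (camera adjusted p = 0.00529, and adjusted p = 0.223 with an estimated correlation). The transmembrane mucin MUC13 rose by 0.88 ± 0.08. E-cadherin, CDH1, rose by 0.60 ± 0.05. Of 20 endoplasmic reticulum chaperones 11 rose, and 11 adjusted over the list alone (camera adjusted p = 4.65e-06, and adjusted p = 0.0644 with an estimated correlation). HERPUD1, which serves protein degradation there, rose by 0.44 ± 0.06 and the chaperone HSPA5 by 0.28 ± 0.04. Of 22 lysosome and autophagy genes 12 rose, and 14 adjusted over the list alone (camera adjusted p = 3.99e-05, and adjusted p = 0.106 with an estimated correlation); the protease CTSD rose by 0.53 ± 0.06. Of the 30 lists tested, 17 passed at the preset correlation and 5 of these with an estimated one.

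**Figure D2:**
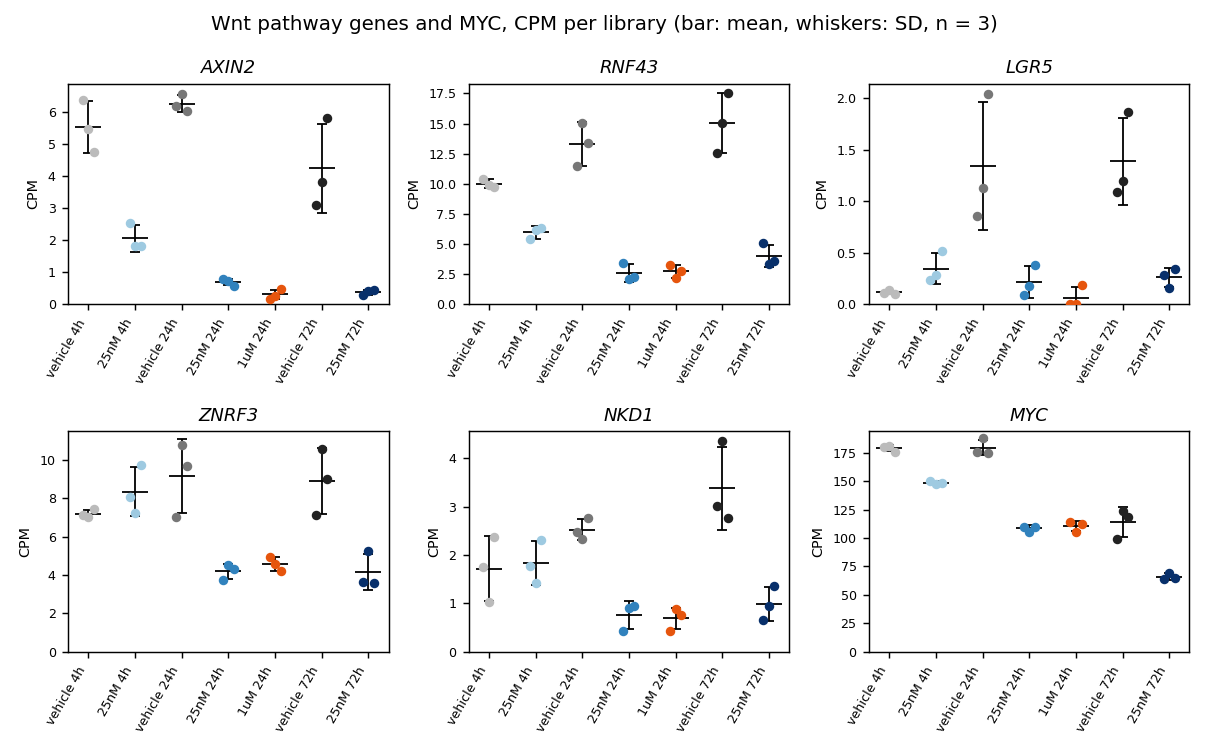
CPM of 6 Wnt feedback and target genes, one point per library and 3 per group; bars show the group mean and whiskers its SD. AXIN2 lies at 4.75 to 6.35 in vehicle and 1.80 to 2.53 with 25 nM at 4 h, and reaches 0.176 to 0.470 with 1 µM at 24 h.

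At 72 h the comparison asks which genes change late. AXIN2, RNF43, ZNRF3, NKD1, LGR5, LGR6, MYC and BMP4 were again low with 25 nM, and CLDN2 and GPX2 stayed low. MMP7, a matrix protease of glands and a Wnt target, the ectodysplasin receptor EDAR and the growth factor-like IGFL2 were low at 72 h and had been called lower at 24 h already. GUCA2A rose, along with REG4, a lectin secreted by gut endocrine and goblet cells, BCAS1, which is abundant in gut epithelium, and CYP3A4, a drug-metabolizing enzyme of liver and gut. The intestinal keratin KRT20 and CDX2, the transcription factor of intestinal identity, rose as well.

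CLDN2 changed by -3.65 ± 0.29 (edgeR adjusted p = 2.68e-10), AXIN2 by -3.47 ± 0.33 (edgeR adjusted p = 5.13e-09), GPX2 by -2.41 ± 0.22 and MMP7 by -2.39 ± 0.19. IGFL2 changed by -2.04 ± 0.13, EDAR by -2.02 ± 0.12, RNF43 by -1.92 ± 0.17 and BMP4 by -1.75 ± 0.09. NKD1 changed by -1.74 ± 0.34, ZNRF3 by -1.07 ± 0.18 and MYC by -0.78 ± 0.06. LGR5, again at a low level, changed by -2.38 ± 0.54. PORCN rose by 0.55 ± 0.10, and CCND1 changed by 0.04 ± 0.04 and was not called. NOTUM changed by -0.86 ± 0.44 and was called only without 25 nM 72 h replicate 1 (-1.40, edgeR adjusted p = 0.0345). GUCA2A rose by 2.95 ± 0.19 (edgeR adjusted p = 7.98e-12), BCAS1 by 2.27 ± 0.15, REG4 by 2.16 ± 0.17, CYP3A4 by 1.99 ± 0.24 and CDX2 by 0.81 ± 0.09. The metallothionein MT1B, whose reads can belong to other metallothionein genes, rose by 3.07 ± 0.76. POC1B-GALNT4, a read-through locus that shares exons with its neighbors, rose by 3.67 ± 1.38. Its call was lost without vehicle 72 h replicate 2 (3.19, edgeR adjusted p = 0.103) or replicate 3 (3.08, edgeR adjusted p = 0.118), and without 25 nM 72 h replicate 1 (3.25, edgeR adjusted p = 0.108) or replicate 2 (3.47, edgeR adjusted p = 0.0824). It was lost under DESeq2 (adjusted p = 0.197) and limma-voom (adjusted p = 0.125) too. edgeR called 5555 genes, 2736 higher and 2819 lower, of which 174 and 302 changed at least 2-fold. The groups did not overlap for 6553 genes (48.2%, against 10% by chance).

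Cell division genes fell at 72 h. All 25 mitosis genes fell, all 25 adjusted over the list alone, with a median of -1.30 (camera adjusted p = 4.38e-70, and adjusted p = 0.000966 with an estimated correlation). MKI67 changed by -1.37 ± 0.07, the kinesin KIF20A by -1.35 ± 0.06, the topoisomerase TOP2A by -1.34 ± 0.06 and the spindle protein TPX2 by -1.17 ± 0.06. All 25 DNA replication and S phase genes fell, all 25 adjusted over the list alone (camera adjusted p = 1.98e-33, and adjusted p = 0.0171 with an estimated correlation). CDC6 changed by -1.38 ± 0.09, thymidylate synthase, TYMS, by -1.30 ± 0.09 and MCM7 by -1.08 ± 0.06. Of 30 MYC-linked ribosome biogenesis genes 29 fell, and 30 adjusted over the list alone (camera adjusted p = 6.98e-18, and adjusted p = 0.0423 with an estimated correlation). CAD, which starts pyrimidine synthesis, changed by -0.97 ± 0.07 and the nucleolar methyltransferase FBL by -0.74 ± 0.07. Of 19 homologous recombination and Fanconi repair genes 17 fell, and 17 adjusted over the list alone (camera adjusted p = 8.30e-11, and adjusted p = 0.0181 with an estimated correlation). FANCD2 changed by -1.15 ± 0.10 and BRCA1 by -1.09 ± 0.10. Histone genes, whose main transcripts lack poly(A) tails, had been fixed as a list on RNA quality. Of 10 histone genes 6 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000524, and adjusted p = 0.0194 with an estimated correlation). A difference in RNA quality between the 72 h groups is thus not excluded and was not tested further. HIST1H2BD rose by 1.32 ± 0.14 and the linker histone HIST1H1C by 1.13 ± 0.10. CDKN1A rose by 0.84 ± 0.07 and BMF by 1.35 ± 0.12.

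Differentiation genes rose at 72 h. Of 14 HNF1 and intestinal differentiation genes 10 rose, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.28e-07, and adjusted p = 0.0171 with an estimated correlation). The galectin LGALS4 rose by 0.55 ± 0.05. Of 22 classical pancreatic cancer subtype genes 15 rose and 1 fell, and 16 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.00e-07, and adjusted p = 0.0859 with an estimated correlation). TFF2 rose by 1.38 ± 0.08 and CDH17 by 0.78 ± 0.04. Of 18 mucins and goblet-type secretory genes 10 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 1.29e-06, and adjusted p = 0.0623 with an estimated correlation). MUC13 rose by 1.17 ± 0.08. Of 14 basal-like subtype genes 7 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.00527, and adjusted p = 0.0423 with an estimated correlation), a call lost with no filter on low counts (adjusted p = 0.0711). The protease CTSV rose by 1.35 ± 0.11, FAM83A of MAPK signaling by 0.91 ± 0.07 and the dehydrogenase DHRS9 by 0.79 ± 0.05. Of 22 lysosome and autophagy genes 17 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 1.29e-06, and adjusted p = 0.0623 with an estimated correlation). The lysosomal channel MCOLN1 rose by 0.91 ± 0.09 and the autophagy receptor SQSTM1 by 0.52 ± 0.05. Of 22 cholesterol synthesis genes 9 fell and 1 rose, and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0300, and adjusted p = 0.451 with an estimated correlation), a call lost with relative log expression scaling (adjusted p = 0.0520). SQLE, an enzyme of this pathway, changed by -0.40 ± 0.05. Of 21 Wnt/beta-catenin target and feedback genes 11 fell and 4 rose, the same adjusted over the list alone (camera adjusted p = 0.00146, and adjusted p = 0.0912 with an estimated correlation). Of the 30 lists tested, 15 passed at the preset correlation and 8 of these with an estimated one.

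Markers of other cell types were measured as well. Of 7 fibroblast markers tested 2 rose at 72 h, the proteoglycans DCN (2.30 ± 0.30) and LUM (1.21 ± 0.06), and 2 adjusted over the list alone (camera adjusted p = 0.00919, and adjusted p = 0.0423 with an estimated correlation), a call lost with no filter on low counts (adjusted p = 0.272). Of 4 leukocyte and endothelial markers tested, the lysosomal protein CD68 rose by 0.79 ± 0.04 and VWF by 1.21 ± 0.25. CD14 rose by 0.80 ± 0.25, a call lost without vehicle 72 h replicate 1 (0.67, edgeR adjusted p = 0.0652) or replicate 3 (0.62, edgeR adjusted p = 0.0848).

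**Figure D3:**
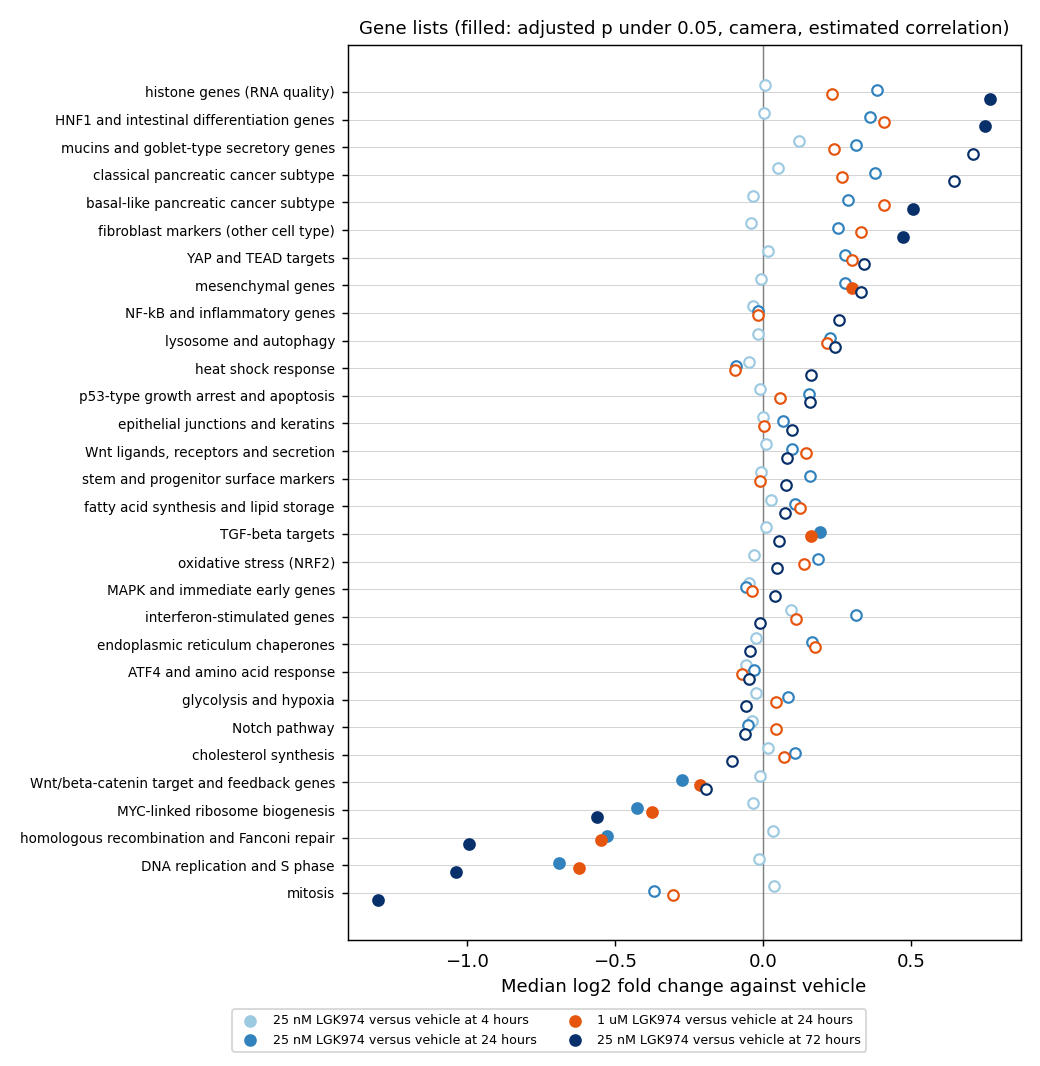
Median log2 fold change of each of the 30 gene lists tested, against vehicle with 25 nM at each time and with 1 µM at 24 h; filled points passed camera with an estimated correlation. Mitosis genes reach -1.30 and DNA replication and S phase genes -1.04 at 72 h with 25 nM, against -0.37 and -0.69 at 24 h.

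With 1 µM at 24 h the comparison asks whether a higher dose against the same vehicle libraries changes the same genes. AXIN2, CLDN2, GPX2, RNF43, BMP4, NKD1, ZNRF3, LGR6 and MYC fell. SDPR, a coat protein of caveolae, fell with them. KRT16, GUCA2A and BCAS1 rose, as did the amino acid transporter SLC7A8 and CYP2B6, a drug-metabolizing enzyme.

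AXIN2 changed by -4.33 ± 0.33 (edgeR adjusted p = 1.06e-09), CLDN2 by -3.54 ± 0.28 (edgeR adjusted p = 1.22e-09), GPX2 by -2.44 ± 0.25 and RNF43 by -2.28 ± 0.19. The level of AXIN2 was low with 1 µM, at 0.176 to 0.470 CPM. SDPR changed by -2.17 ± 0.20, BMP4 by -1.96 ± 0.08, NKD1 by -1.86 ± 0.38, LGR6 by -1.26 ± 0.08 and MYC by -0.70 ± 0.06. LGR5 had a mean of 0.0626 CPM here, with 0 counts in 2 of the 3 libraries, so no fold is given for it. KRT16 rose by 1.69 ± 0.10 (edgeR adjusted p = 4.72e-12), GUCA2A by 1.42 ± 0.33, CYP2B6 by 1.41 ± 0.26, SLC7A8 by 1.39 ± 0.23 and BCAS1 by 1.33 ± 0.22. PORCN changed by 0.25 ± 0.10 (edgeR adjusted p = 0.0626) and was called without 1 µM 24 h replicate 2 (0.33, edgeR adjusted p = 0.0175). edgeR called 3625 genes, 2151 higher and 1474 lower, of which 36 and 85 changed at least 2-fold. The groups did not overlap for 5488 genes (40.3%, against 10% by chance).

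All 25 DNA replication and S phase genes fell with 1 µM, all 25 adjusted over the list alone (camera adjusted p = 3.98e-31, and adjusted p = 0.0319 with an estimated correlation). UHRF1, which copies DNA methylation, changed by -0.94 ± 0.11. Of 30 MYC-linked ribosome biogenesis genes 24 fell, and 27 adjusted over the list alone (camera adjusted p = 1.36e-19, and adjusted p = 0.0461 with an estimated correlation). Of 21 Wnt/beta-catenin target and feedback genes 11 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 1.78e-09, and adjusted p = 0.0260 with an estimated correlation). Of 19 homologous recombination and Fanconi repair genes 16 fell, and 17 adjusted over the list alone (camera adjusted p = 3.43e-10, and adjusted p = 0.0338 with an estimated correlation). Of 9 mesenchymal genes 6 rose, and 6 adjusted over the list alone (camera adjusted p = 0.000279, and adjusted p = 0.0458 with an estimated correlation). The integrin ITGA5 rose by 0.57 ± 0.10 and the transcription factor SNAI2 by 0.50 ± 0.06. Of 17 TGF-beta targets 7 rose and 2 fell, and 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0127, and adjusted p = 0.0461 with an estimated correlation), a call lost with no filter on low counts (adjusted p = 0.0536). Of the 30 lists tested, 15 passed at the preset correlation and 6 of these with an estimated one.

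The direct comparison of 1 µM with 25 nM asks what the higher dose adds. Of the genes induced by the aryl hydrocarbon receptor, a sensor of foreign compounds, 4 fell: its repressor AHRR, the oxidases CYP1B1 and CYP1A1, and TIPARP, which feeds back on the receptor. A set of 8 other targets of the receptor was drawn up after the dose results were seen and defined to hold no called gene. That none of the 8 was called (edgeR adjusted p = 0.383 to 0.984) was thus fixed in advance. It does not limit the response to these 4 genes. ALDH1A3, which makes retinoic acid, the guanine deaminase GDA, the adhesion receptor GPR110 and UGT1A1, a glucuronidation enzyme that shares exons with other UGT1A genes, fell as well. ENG, a TGF-beta co-receptor, and RBM3, a cold-induced RNA-binding protein, rose. CYP1A1 and TIPARP lie outside the naming rule and were picked after their values were seen.

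ALDH1A3 changed by -0.37 ± 0.04 (edgeR adjusted p = 8.08e-06), GDA by -0.37 ± 0.04 (edgeR adjusted p = 6.48e-05), AHRR by -0.68 ± 0.09 (edgeR adjusted p = 0.000508) and GPR110 by -0.42 ± 0.06 (edgeR adjusted p = 0.00148). These 4 kept their calls without each of the 6 libraries in turn. CYP1B1 changed by -0.88 ± 0.15 (edgeR adjusted p = 0.00775), a call lost without 25 nM 24 h replicate 1 (-0.84, edgeR adjusted p = 0.0812), without 25 nM 24 h replicate 2 (-0.82, edgeR adjusted p = 0.0538) and without 1 µM 24 h replicate 3 (-0.80, edgeR adjusted p = 0.104), and with only these groups in the fit (edgeR adjusted p = 0.0896). TIPARP changed by -0.33 ± 0.06 (edgeR adjusted p = 0.0161), a call lost without 25 nM 24 h replicate 1 (-0.30, edgeR adjusted p = 0.178), 1 µM 24 h replicate 1 (-0.32, edgeR adjusted p = 0.0726) or 1 µM 24 h replicate 3 (-0.28, edgeR adjusted p = 0.183). CYP1A1 changed by -1.77 ± 0.34 (edgeR adjusted p = 0.0332) and lost its call without any one of the 6 libraries, with values of -1.86 to -1.61 and edgeR adjusted p of 0.0722 to 0.191. UGT1A1 changed by -0.49 ± 0.09 (edgeR adjusted p = 0.0161), lost without 25 nM 24 h replicate 1 (-0.45) or 2 (-0.47) and without 1 µM 24 h replicate 2 (-0.49) or 3 (-0.46). ENG rose by 0.34 ± 0.07, a call lost without any one of the 6 libraries (edgeR adjusted p = 0.0812 to 0.307) and with only these groups in the fit (edgeR adjusted p = 0.131). RBM3 rose by 0.26 ± 0.05, a call lost without 25 nM 24 h replicate 1 (0.27), 2 (0.26) or 3 (0.26) and without 1 µM 24 h replicate 2 (0.20) or 3 (0.27), and with only these groups in the fit (edgeR adjusted p = 0.104).

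Against vehicle, CYP1A1 changed by -1.27 ± 0.36, CYP1B1 by -1.09 ± 0.14, AHRR by -0.65 ± 0.09 and TIPARP by -0.51 ± 0.06 with 1 µM, all called. With 25 nM at 24 h CYP1A1 changed by 0.50 ± 0.29, CYP1B1 by -0.21 ± 0.13 and AHRR by 0.03 ± 0.09, none called, and TIPARP fell by 0.18 ± 0.06. With 25 nM at 72 h CYP1B1 fell by 0.65 ± 0.14 (edgeR adjusted p = 0.000634), and CYP1A1 (0.54 ± 0.27), AHRR (-0.15 ± 0.09) and TIPARP (-0.10 ± 0.06) were not called. The Wnt genes did not pass between the doses: AXIN2 changed by -1.18 ± 0.47 (edgeR adjusted p = 0.638), RNF43 by 0.06 ± 0.24, BMP4 by 0.02 ± 0.10, MYC by 0.03 ± 0.06 and CLDN2 by -0.03 ± 0.41. AXIN2 was at a low level at both doses, 0.574 to 0.769 CPM with 25 nM and 0.176 to 0.470 with 1 µM. A further fall of AXIN2 at 1 µM is thus left open. edgeR called 11 genes, 2 higher and 9 lower, with 968 at an unadjusted p under 0.05 (7.12%). DESeq2 called 18, of which 7 were among the 11, with TIPARP the only one of the 4 receptor targets. It gave AHRR, CYP1B1, CYP1A1 and ENG no adjusted p, since its own filter on mean counts left 4861 genes. limma-voom called 10, without CYP1A1 (-1.71, adjusted p = 0.0694). The edgeR count was 4 without 25 nM 24 h replicate 1, 7 without 25 nM 24 h replicate 3, 6 without 1 µM 24 h replicate 2, 4 without 1 µM 24 h replicate 3 and 54 with no filter on low counts. The groups did not overlap for 1837 genes (13.5%, against 10% by chance). Of 30 lists 4 passed at the preset correlation and 0 with an estimated one. Without 25 nM 24 h replicate 1, 2 or 3, or 1 µM 24 h replicate 1 or 2, the list count was 0, 8, 1, 2 and 0. In simulated doses camera passed 4 lists that had not been changed as a set, as many as here. The simulated doses held 225 changed genes, some of which may be list members. The simulation thus gives no rate of false passes for the lists here.

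**Figure D4:**
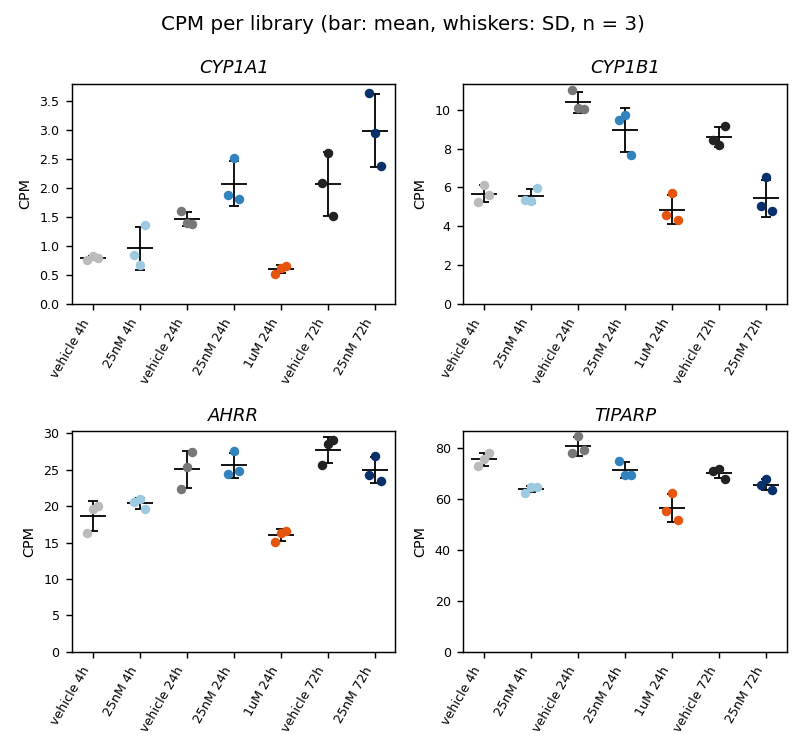
CPM of CYP1A1, CYP1B1, AHRR and TIPARP, one point per library and 3 per group; bars show the group mean and whiskers its SD. With 1 µM against 25 nM at 24 h the log2 changes are -1.77, -0.88, -0.68 and -0.33.

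Both doses at 24 h shared 1613 genes that rose and 1153 that fell, where independent lists of these sizes give 328 and 175, and 0 genes went in opposite directions. The doses were compared with the same 3 vehicle libraries. In 20 simulations of unchanged groups against those libraries, 0 calls were shared on average. The covariance of fold changes across genes was 0.109, against 0.000906 in the simulations. The simulated groups were drawn around the mean of these same vehicle libraries, so they lack the vehicle error that both doses share. Their low values were thus fixed in advance, and the simulations cannot show how much the shared controls add. The vehicle libraries are too few to be split with enough in each part, so a part of the excess may come from the shared controls. CLDN2, AXIN2, RNF43 and BMP4 fell at both doses, and KRT16 and GUCA2A rose at both.

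**Figure D5:**
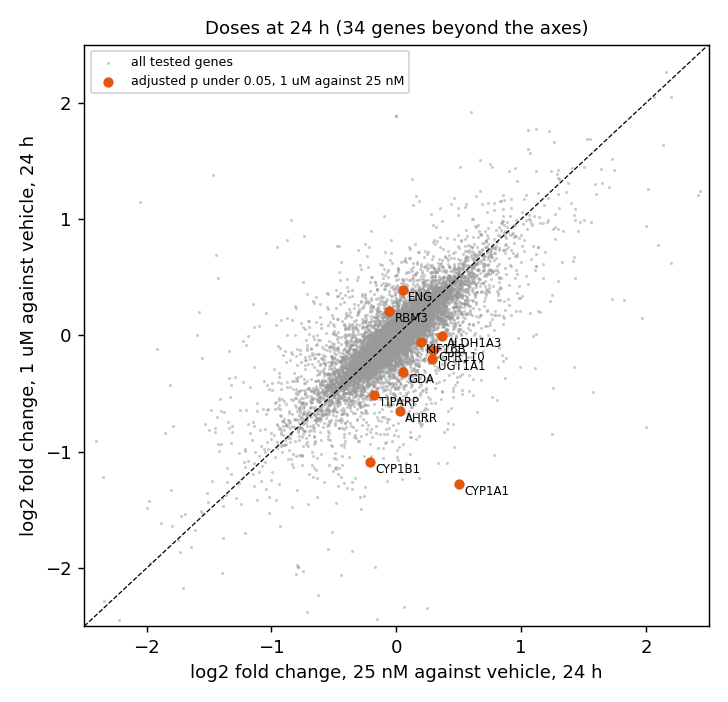
Log2 fold change against vehicle at 24 h with 1 µM (vertical) against 25 nM (horizontal), one point per gene, with the genes called between the doses named and 34 genes beyond the axes at 2.5. The 1613 genes that rose and 1153 that fell at both doses lie along the diagonal, and CYP1A1, CYP1B1 and AHRR lie below it.

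The difference between the effects at 24 h and at 4 h was tested as an interaction. The effect on CLDN2, GPX2, RAB15, AXIN2, RNF43, ZNRF3 and MYC was lower at 24 h than at 4 h, as was that on NREP, a protein of cell migration. The effect on CYP2B6 was higher. These differences measured -3.55 ± 0.36 for CLDN2 (edgeR adjusted p = 3.68e-07), -2.37 ± 0.32 for GPX2, -2.04 ± 0.24 for RAB15, -1.89 ± 0.34 for NREP, -1.74 ± 0.39 for AXIN2, -1.60 ± 0.26 for RNF43, -1.35 ± 0.25 for ZNRF3 and -0.46 ± 0.08 for MYC. The difference for CYP2B6 was 2.89 ± 0.60 (edgeR adjusted p = 0.00186). edgeR called 1844 genes, 1074 higher and 770 lower. Of 12 lists that passed at the preset correlation, 5 passed with an estimated one, in a test added after the data were seen. These were S phase (0 higher, 23 lower of 25, adjusted p = 0.0253 with an estimated correlation), homologous recombination (0 and 12 of 19, adjusted p = 0.0253), Wnt target (1 and 11 of 21, adjusted p = 0.0253) and ribosome biogenesis genes (0 and 22 of 30, adjusted p = 0.0299), all lower, and endoplasmic reticulum chaperones, higher (10 and 0 of 20, adjusted p = 0.0299).

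Between 72 h and 24 h the effect on mitosis genes became more negative. All 25 were called lower in the interaction, with a median difference of -0.89 (camera adjusted p = 0.000502 with an estimated correlation). It was the 1 list of 19 past the preset threshold that also passed with an estimated correlation. The effect on CORO1A, an actin-binding protein, was lower at 72 h (-1.40 ± 0.32, edgeR adjusted p = 0.00608), and that on the membrane mucin MUC4 was higher (1.43 ± 0.36, edgeR adjusted p = 0.0133). The effect on CCND1 differed by 0.24 ± 0.06 (edgeR adjusted p = 0.0125). AXIN2 (-0.32 ± 0.48), RNF43 (0.42 ± 0.27), ZNRF3 (0.06 ± 0.26) and MYC (-0.05 ± 0.08) showed no called difference between these times. edgeR called 1111 genes, 443 higher and 668 lower; with relative log expression scaling the split was 634 and 493. The calls against vehicle at 24 h and 72 h shared 1483 genes that rose and 1249 that fell, where independent lists give 418 and 334, and 63 went in opposite directions.

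Vehicle cells changed with time in culture, which is the background to every treatment effect. From 4 h to 24 h the collagenase MMP1 and the lipid transporter MFSD2A fell, and the surface protein SUSD2 and PPP1R14D, a phosphatase inhibitor of gut epithelium, rose. Genes of the unfolded protein response fell and genes of lipid synthesis rose. MMP1 changed by -3.01 ± 0.08 (edgeR adjusted p = 9.64e-19), MFSD2A by -2.84 ± 0.13, SUSD2 by 3.82 ± 0.56 and PPP1R14D by 2.92 ± 0.22. PORCN fell by 0.63 ± 0.09. All 20 endoplasmic reticulum chaperones fell, all 20 adjusted over the list alone (camera adjusted p = 3.31e-20, and adjusted p = 0.00316 with an estimated correlation), with HERPUD1 at -1.35 ± 0.06 and HSPA5 at -1.18 ± 0.04. Of 17 ATF4 and amino acid response genes 13 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 8.50e-06, and adjusted p = 0.0378 with an estimated correlation); the asparagine synthetase ASNS changed by -1.67 ± 0.09. Of 22 cholesterol synthesis genes 20 rose, and 20 adjusted over the list alone (camera adjusted p = 3.53e-11, and adjusted p = 0.0438 with an estimated correlation), with FDFT1 at 0.94 ± 0.04. Of 23 fatty acid synthesis and lipid storage genes 16 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 5.57e-06, and adjusted p = 0.0378 with an estimated correlation). edgeR called 7576 genes, 3652 higher and 3924 lower, and the groups did not overlap for 8431 (62.0%, against 10% by chance).

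From 24 h to 72 h in vehicle most mucin and goblet-type genes rose and most oxidative stress genes fell, though neither list passed with an estimated correlation. CYP3A4 rose by 4.45 ± 0.46 (edgeR adjusted p = 2.27e-08), the membrane scaffold PDZK1 by 2.94 ± 0.26, complement factor CFI by 2.85 ± 0.22, REG4 by 2.84 ± 0.27, PCK1 by 2.81 ± 0.28 and MUC13 by 2.34 ± 0.08. The metallothioneins MT1A (-4.24 ± 0.17) and MT1G (-3.03 ± 0.11), which can share reads with each other, fell. MYC changed by -0.66 ± 0.06 and CCND1 by -0.46 ± 0.04. Of 18 oxidative stress (NRF2) genes 16 fell, and 16 adjusted over the list alone (camera adjusted p = 2.81e-19, and adjusted p = 0.0523 with an estimated correlation), with heme oxygenase, HMOX1, at -1.16 ± 0.07. Of 18 mucins and goblet-type secretory genes 12 rose and 1 fell, and 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.07e-11, and adjusted p = 0.0523 with an estimated correlation). Of 25 mitosis genes 24 rose, and 25 adjusted over the list alone (camera adjusted p = 1.39e-07, and adjusted p = 0.209 with an estimated correlation). edgeR called 5686 genes, 2917 higher and 2769 lower, and the groups did not overlap for 6644 (48.8%, against 10% by chance). Of 30 lists 15 passed at the preset correlation and 0 with an estimated one.

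The authors' own tables, deposited for 4 comparisons, list adjusted p-values for all their genes. At 4 h they place 9 genes past 0.05, 4 higher and 5 lower, among them MYC (-0.21, adjusted p = 0.000546), BMP4 (-0.24, adjusted p = 0.000682) and AXIN2 (-0.12, adjusted p = 0.0409). At 24 h they place 2679 genes past 0.05 with 25 nM, of which 2621 were called in the same direction by edgeR here and 0 in the opposite one. At 72 h they place 3890, of which 3871 were called in the same direction and 0 in the opposite one. Between the doses they place 18, of which 7 were called here in the same direction. Their log2 fold changes for AXIN2 were -1.40 at 24 h and -1.76 at 72 h, narrower than those computed here, as at 4 h (-0.12 against -1.41). These deposited values may be shrunken estimates, which the headers do not state, so their sizes are not comparable with the fold changes from the counts.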

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

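The difference of the effect of 25 nM LGK974 between times was tested as an interaction with edgeR, and a called difference flagged each result here. Between 24 h and 4 h, 1844 genes were called. The difference was -3.55 for CLDN2, -2.37 for GPX2, -2.04 for RAB15, -1.89 for NREP, -1.74 for AXIN2, -1.60 for RNF43, -1.35 for ZNRF3, -0.46 for MYC and 2.89 for CYP2B6, calls kept without each library in turn. LGR5 had a difference of -4.07, but its level in vehicle at 4 h is about 1 count per library, at the floor, so the fitted value depends on the prior count. NKD1 differed by -1.87, a call lost without 25 nM 24 h replicate 1 (-1.57, adjusted p = 0.0574). PORCN differed by 0.44, lost without vehicle 4 h replicate 1 (0.37, adjusted p = 0.0784), vehicle 24 h replicate 2 (0.42, adjusted p = 0.0608) or 25 nM 24 h replicate 1 (0.41, adjusted p = 0.0691). CCND1 differed by -0.19, lost without vehicle 4 h replicate 1 (-0.20) or 3 (-0.17), 25 nM 4 h replicate 3 (-0.15), vehicle 24 h replicate 1 (-0.18) or 2 (-0.17), or 25 nM 24 h replicate 1 (-0.17) or 3 (-0.18).

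Read-through and pseudogene-type loci were called in the same test and share reads with their neighbors or relatives. CORO7-PAM16 differed by 6.01, and by 1.01 without 25 nM 24 h replicate 3 (adjusted p = 0.931); its call was lost under DESeq2 (adjusted p = 0.0779) and limma-voom (adjusted p = 0.231). LOC100093631 differed by 3.84, lost without vehicle 4 h replicate 1 (3.42) or 3 (3.32) or vehicle 24 h replicate 2 (3.65), under DESeq2 (adjusted p = 0.0578) and under limma-voom (2.05, adjusted p = 0.443). GJA9-MYCBP differed by 3.37, lost without vehicle 4 h replicate 1 (3.35), 2 (3.49) or 3 (3.26), 25 nM 4 h replicate 2 (2.84), vehicle 24 h replicate 2 (3.30) or 3 (2.81), or 25 nM 24 h replicate 1 (3.18) or 2 (2.72), under DESeq2 (adjusted p = 0.228) and under limma-voom (adjusted p = 0.397).

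Between 72 h and 24 h, 1111 genes were called. The difference was -1.40 for CORO1A, 1.43 for MUC4 and 0.24 for CCND1, calls kept without each library in turn. C6orf222 differed by 1.45, lost without vehicle 24 h replicate 3 (0.99, adjusted p = 0.116), and GAS2L3, a cytoskeletal linker of dividing cells, by -1.53, lost without 25 nM 24 h replicate 2, where the difference shrank by over 1.5 times (adjusted p = 0.104). SNHG3, a host of small nucleolar RNAs, differed by -1.35, lost without vehicle 24 h replicate 1 (-1.26), 25 nM 24 h replicate 2 (-1.15), vehicle 72 h replicate 3 (-0.97) or 25 nM 72 h replicate 3 (-1.15). GTF2H2, which has near-identical copies, differed by -1.52, lost without vehicle 24 h replicate 1 (-1.35) or 2 (-1.45), 25 nM 24 h replicate 2 (-1.14), vehicle 72 h replicate 1 (-1.36) or 2 (-1.51), or 25 nM 72 h replicate 1 (-1.39) or 3 (-1.45), and under limma-voom (adjusted p = 0.0683). MT1B, which shares reads with other metallothioneins, differed by 2.86, lost without vehicle 24 h replicate 1 (2.82) or 3 (2.86), 25 nM 24 h replicate 2 (2.88) or 3 (2.82), vehicle 72 h replicate 1 (2.33) or 2 (2.49), or 25 nM 72 h replicate 1 (2.96), 2 (2.72) or 3 (2.85), under DESeq2 (adjusted p = 0.0951) and with no filter on low counts (adjusted p = 0.0543). ABCA6, a lipid transporter, differed by 1.53, lost without vehicle 24 h replicate 2 (1.56) or 3 (1.30), 25 nM 24 h replicate 2 (1.45) or 3 (1.30), vehicle 72 h replicate 2 (1.62) or 3 (1.24), or 25 nM 72 h replicate 1 (1.44) or 3 (1.44), and with only these groups in the fit (adjusted p = 0.0607).

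For the differences between times, other groupings of the same libraries gave the same count or more. In 100 splits, 7 reached 1844 for 24 h against 4 h, the real one included, and the highest other count was 2323. For 72 h against 24 h, 8 of 100 splits reached 1111, and the highest other count was 6149. By this share chance cannot be excluded for either count. Of the other splits that reach them, 6 for each difference keep the real grouping of 1 time and with it that time's effect. The 1 further split, with 6149, keeps both groupings with the labels swapped at 1 time, so that the effects at 24 h and 72 h add up. Among the 84 splits that keep neither time, the highest counts were 1 and 0.

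For a comparison of 2 groups only 10 splits exist, too few for a share under 0.05. The real count was reached by 10 splits at 4 h (real 0, highest other 1). It was reached by 1 split, the real one, at 24 h (real 3687, highest other 3), at 72 h (real 5555, highest other 1), with 1 µM against vehicle (real 3625, highest other 0) and between the doses (real 11, highest other 2). The same held in vehicle for 24 h against 4 h (real 7576, highest other 0) and for 72 h against 24 h (real 5686, highest other 0).

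Lower activity of the aryl hydrocarbon receptor at 1 µM was weighed by a test chosen after the dose results were seen. CYP1A1, CYP1B1, AHRR and TIPARP were lower at 1 µM than at 25 nM. Without each of the 6 libraries all 4 genes stayed at -0.28 or below, so no 1 library set the sign of their difference. The 4 genes had been picked as called, which made such an outcome likely. Their calls did depend on single libraries: CYP1A1 kept 0 of 6 calls, CYP1B1 and TIPARP 3 of 6 each and AHRR 6 of 6. The 8 other targets of the receptor were defined to hold no called gene. Of these, 7 were lower, with a median of -0.19 (camera p = 0.00511 with an estimated correlation). That p is not adjusted over lists, and 0 of the 30 fixed lists passed between the doses with an estimated correlation. UGT1A6, 1 of the 8, shares exons with UGT1A1, which was itself called lower. These lower values go with lower activity of the receptor at 1 µM but do not establish it. CYP1B1 also fell with 25 nM at 72 h (-0.65), and the test does not say whether LGK974 acts on the receptor.

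The step from 0 called genes at 4 h to 3687 at 24 h was weighed next. Without 25 nM 4 h replicate 2, 0 genes were called at 4 h. At 24 h, with a library left out in turn, 2837 to 3432 genes were still called. This argues against that replicate hiding changes as many and as large as those at 24 h. Whether it hides fewer or smaller changes cannot be told, since leaving out a library itself lowers the count. An early fall of the genes that fall later cannot be told from none: of 87 genes that fell at least 2-fold at 24 h, 48 were lower at 4 h (camera p = 0.398 with an estimated correlation). Of 47 genes that rose at least 2-fold at 24 h, 29 were higher at 4 h, with a median of 0.33 (camera p = 0.0178 at the preset and p = 0.101 with an estimated correlation), which leaves an early rise open too.

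A rise in vehicle cells alone as the source of the larger fall of mitosis genes at 72 h was weighed by a test chosen after the results were seen. It is excluded, since the median change of the 25 mitosis genes between 24 h and 72 h was -0.52 with 25 nM, with 24 called lower, and 0.39 in vehicle, with 24 called higher. The exclusion rests on these members, since neither change passed as a list with an estimated correlation (camera p = 0.0870 with 25 nM and p = 0.0907 in vehicle). That 1 vehicle 72 h library sets the difference is excluded too, with a median of -0.85 or lower without each of the 3 libraries. The test of the difference between the times (camera p = 1.67e-05 with an estimated correlation) uses the genes and libraries that gave the pattern. It restates the larger fall at 72 h, of which the rise in vehicle (0.39) is a part. It therefore cannot decide whether an effect on cell division grows with time.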

How the results depend on the processing

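No result reversed. Of 348 gene results, 314 kept their side of the threshold under every alternative fit that gave them an adjusted p, among them 259 of 283 called ones. DESeq2 gave 321 of the 348 an adjusted p, and the 2-fold and 0.01 thresholds were applied to counts only. Of 5026 values 4879 were the same, 124 weaker and 23 stronger. Of 210 list results, 96 kept theirs, among them 21 of 86 called ones; of 2728 values 2506 were the same, 137 weaker and 85 stronger. With a change of at least 2-fold the counts were 134 at 24 h, 476 at 72 h, 121 with 1 µM, 1 between doses, 102 for 24 h against 4 h, 73 for 72 h against 24 h, 917 and 573 in vehicle from 4 h to 24 h and from 24 h to 72 h, 60 shared between times and 66 between doses, as the stricter threshold implies. With an adjusted p under 0.01 they were 2383 at 24 h, 2316 with 1 µM, 5 between doses, 913 and 521 for the differences between times, 1819 shared between times and 1801 between doses, for the same reason.

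For the other moves the cause was not tested. At 4 h DESeq2 called 6, limma-voom 2, no filter 28, the stricter filter 1 and only the groups compared 11, against 0. Between doses DESeq2 called 18 and no filter 54, against 11. With an estimated correlation the lists past the threshold were 0 at 4 h, 5 at 24 h, 8 at 72 h, 6 with 1 µM, 0 between doses, 5 in vehicle from 4 h to 24 h and 0 from 24 h to 72 h, against 5, 17, 15, 15, 4, 15 and 15. With fry they were 0 at 4 h, 26 at 24 h, 0 between doses and 26 in vehicle from 4 h to 24 h; at 4 h without a filter they were 3. With relative log expression scaling the split for 72 h against 24 h was 634 higher and 493 lower, against 443 and 668, so the balance of directions there depends on the scaling.

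Without 1 library in turn, with fewer samples in the fit, the counts were 0 to 1 at 4 h, 2837 to 3432 at 24 h, 4685 to 5464 at 72 h, 2806 to 3285 with 1 µM, 4 to 12 between doses, 1367 to 1963 for 24 h against 4 h, 790 to 1413 for 72 h against 24 h, and 6915 to 7089 and 4858 to 5407 in vehicle. Shared calls were 2177 to 2763 between times and 2170 to 2594 between doses. Lists past the threshold were 1 to 7 at 4 h, 16 to 20 at 24 h, 15 to 16 at 72 h, 12 to 16 with 1 µM, 0 to 8 between doses, and 14 to 16 and 13 to 15 in vehicle. Without 25 nM 4 h replicate 2 and vehicle 72 h replicate 3 together, the lowest on the fourth component, an alternative chosen after the data were seen, the counts were 0, 3838, 4759, 3793, 15, 1625, 947, 7670 and 5386, in the order above.

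With the replicate number as a block the counts were 0, 3714, 5596, 3725, 14, 1994, 1224, 7591 and 5741, in the same order, all within 1.5 times. The block changed the calls of GJA9-MYCBP for 24 h against 4 h (adjusted p = 0.0529), AXIN2 in vehicle from 24 h to 72 h (adjusted p = 0.0503) and PORCN with 1 µM (0.24, adjusted p = 0.0338), and of no other named gene. Libraries with the same number did not deviate together: over 63 pairs the correlation was -0.199 to 0.0749, and 5 of 21 libraries were closest to their own number. At 9019030 to 14620500 counts per library, genes near the floor such as LGR5 have wide errors.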

Other observations

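Single genes of further pathways were called under treatment, while most of these pathways did not pass as lists. At 72 h the amino acid synthesis genes ASNS (-0.82 ± 0.10), asparagine synthetase, and PSPH (-0.87 ± 0.08), of serine synthesis, fell, while of 17 ATF4 and amino acid response genes 4 rose and 6 fell, and 5 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.216). The receptor kinase AXL rose by 0.52 ± 0.05 and tissue factor, F3, by 0.58 ± 0.08. Of 22 p53-type growth arrest and apoptosis genes 9 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.104). Of 22 interferon-stimulated genes 4 rose and 3 fell at 72 h (camera adjusted p = 0.966), so neither list passed. Of 18 oxidative stress (NRF2) genes 12 rose at 24 h, and 12 adjusted over the list alone (camera adjusted p = 0.000149, and adjusted p = 0.223 with an estimated correlation), with ferritin light chain, FTL, at 0.32 ± 0.04.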
